A study of Mus musculus with 3 samples.

How the data were processed

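Total RNA from the ovaries of C57BL/6 mice was compared on 3 spotted arrays. Per the labels, each array carried amplified and labelled RNA of 1 treated group in Cy5 (cyclophosphamide alone, or cyclophosphamide followed by adipose-derived stem cells into a vein or into both ovaries) and RNA of untreated mice in Cy3. The labels do not say how many animals gave RNA to an array, whether the WT RNA was the same pool on all arrays, or the sex of the cell donors. Each group had 1 array and the dyes were not exchanged.

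The deposited scanner files hold, per the file headers, the median intensity of each spot and the median and SD of its local background in the red (Cy5) and green (Cy3) channel, neither background-subtracted nor normalized, made by image analysis with LuxScan 3.0 per the series' design text. The deposited ratio column equals the Cy5 spot median over the Cy3 spot median without background subtraction, within 1% in 100% of spots on each array, and was used only for that check. The authors' processed values are log2 ratios of Cy5 over Cy3 per spot, normalized within each array by a method not given in the sources used here. Their scale and direction were settled by comparison: over spots with more than 500 intensity units above background in both channels, they correlated with the log2 of the background-subtracted ratio with r of 0.966 (POF), 0.955 (ADSC-iv) and 0.943 (ADSC-ovary), and their medians were 0.04, 0.0082 and 0.02. A flag column holds 100 or -100 for each spot, and its meaning is not stated. The flag was 100 on 10006, 10950 and 10367 of 33696 spots. Among gene probes, 99.8%, 99.6% and 99.7% of those with a flag of 100 were above background in at least 1 channel, against 15.2%, 16.2% and 16.6% of the others.

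Each array has 31920 gene probes and 1776 control spots, among them 768 blanks. A name stands on 24392 probes, and 7528 have none and were left out of the gene values. Of 19518 array names, 14166 were matched to a current gene symbol, 3898 to a gene that had the name as a synonym, and 1454 were kept as they stood, which gave 19459 genes. A table of RefSeq genes (mouse assembly GRCm38.p6) served for names only.

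Intensities were background-corrected with normexp (offset 50) and log2 ratios were normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Probes of a gene were averaged. A spot counted as above background when its median exceeded the local background median by more than 2 background SDs, and a gene was measured in a comparison when at least 1 compared channel was above background on each array used. In comparisons with WT, a gene not above background in WT was thus measured only if the treated channel was. This favours positive ratios in lists of genes that are dim in WT, and random lists were not matched on it. Spots with a flag of -100 were kept. Comparisons with WT used the log2 ratio of 1 array, and comparisons of treated groups used the difference of 2 arrays' ratios. Single-channel values were normalized between arrays by quantiles of mean intensity (Aquantile). Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Before normalization the median log2 ratios were -0.18, -0.25 and -0.25. Only 2 Cy5 probes per array reached the scanner's limit of 65535. Over 48 spots each, the actin, Gapd, Ldha and Rpl5 controls had SDs of 0.07 to 0.17 log2 units, and the median SD between probes of a gene was 0.13 to 0.15 over 898 genes.

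With 1 array per group no test between groups was made and no p-value was computed. Genes with an absolute log2 value of at least 1 (2-fold) were counted. For each of 28 fixed gene lists, the median of the measured members (at least 5) was ranked among the medians of 10000 random lists of equal size, drawn from the same 20 bins of mean intensity with seed 1, and a list stood apart under the 2.5th or over the 97.5th percentile. The Y-linked list had too few measured genes, which left 27. Lists share up to 3 genes. Lists are not controlled for co-expression, so the ranks describe these arrays only. The genes named are the 12 with the largest positive and the 12 with the largest negative values in the comparisons of POF with WT and of each ADSC group with POF, and 5 and 5 in the other comparisons. They were ranked among genes with a proper symbol, above background in both channels, with a flag of 100, brighter than the median of such genes and with all probes of the same sign. Up to 4 members per list with the largest absolute values were added, less 1 gene that is not reported here, and 3 bounds each way for genes above background on only 1 side. Gdf9, Figla, Zp1, Zp2, Zp3 and Srebf2 fall outside this rule and were chosen after their values were seen. Change toward WT was read in genes picked on the POF array and, for comparison, in genes picked on the other arrays. Correlations between ratios that share WT were set beside 100 simulations of unchanged groups.

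The groups, comparisons, lists, thresholds, rule for named genes and all but 1 of the other settings tried were fixed before the data were examined. Chosen afterwards were the limit of 2 background SDs, the keeping of spots with a flag of -100, the 16 gene families of the closing section, the patterns weighed there, the remarks on H2-Ea and Y-linked genes, and the average over a gene's probes above background. A further test of the cytokine pattern, meant to bear on dye bias, was run and dropped after its result was seen, because it only measured the pattern again and a dye effect cancels between arrays labelled the same way. The alternatives tried were no background correction, plain subtraction, a normexp offset of 16, median centring, loess per print block (span 0.4), scaling to equal spread, the authors' values, a filter on both channels, no filter, the brightest probe, leaving out spots with a flag of -100, a 1.5-fold threshold, quantile normalization of each channel alone, and random lists not matched on intensity.

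The steps were tested on simulated data with 200 changed genes and a log2 noise SD of 0.25. Genes with a true log2 fold of 1.5 passed 2-fold in 72 of 95 cases, both for ADSC-iv against WT (53 of 54 among brighter and 19 of 41 among dimmer genes) and for ADSC-iv against POF. Genes with a true log2 fold of 0.75 passed in 5 of 100 and 12 of 100 cases, and unchanged genes in 1 of 9250 and 13 of 8863. The criterion for this check was changed after it had failed. It first asked for 80% of the genes at 1.5 (75.8% passed), then for brighter genes' medians within 0.15 of the true fold (0.163 off at most), then for medians within 0.1 of the fold expected after the intensity that normexp adds (0.144 off at most). None was met, nor was a version of the last with the offset of 50 alone. The criterion in use asks that the slope of measured on expected folds lies within 0.1 of 1, and it was 0.967 and 0.981. On the true folds the slopes were only 0.818 and 0.827, so folds are understated, mostly for dim genes. On the real arrays normexp added 87.6, 90.2 and 93.0 intensity units in Cy5 and 149, 150.1 and 163 in Cy3. The remaining gap was not explained. No setting of the analysis was changed because of it. Random lists of 20 unchanged genes stood apart in 11 of 300 cases (3.67%), and lists shifted by 0.4 in 299 of 300.

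Bounds between an ADSC array and the POF array were computed but are not given as folds, because the WT channel of the same spots moved the same way. Sequences and positions of the probes were not used here.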

Results

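Gene expression was measured in mouse ovaries after chemotherapy with and without a transplant of adipose-derived stem cells (ADSC), a population of mesenchymal cells grown from fat tissue. The C57BL/6 mice formed 4 groups: untreated animals (WT), animals given cyclophosphamide, an alkylating drug used to model premature ovarian failure (POF), and POF animals that received ADSC either into a vein (ADSC-iv) or directly into both ovaries (ADSC-ovary). Ovaries were collected 1 week after treatment, and the labels do not say how many animals gave RNA to each array. There were 3 arrays with 31920 probes each, and every array carried the RNA of 1 treated group in Cy5 and WT RNA in Cy3. With 1 array per group and no exchange of dyes there is no replicate check on any difference below, no p-value can be given, and the number of arrays limits the precision. All values are log2 ratios, or differences of log2 ratios, of these arrays.

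Of the probes, 39.9% gave a signal above background in at least 1 channel on the POF array, 43.4% on the ADSC-iv array and 42.4% on the ADSC-ovary array. None of the 768 blank spots did so (0 on each array). WT was the only group present on more than 1 array, and the labels do not say whether its RNA came from 1 pool. Over 8946 genes, the Cy3 signal of the WT RNA differed between the POF and ADSC-iv arrays with an SD of 0.24 log2 units and by at least 2-fold in 30 genes. The Cy5 signals of the treated ovaries differed between the same arrays with an SD of 0.38, and by at least 2-fold in 138 genes. For the POF and ADSC-ovary arrays the WT channel had an SD of 0.27 and 40 genes at 2-fold, and the treated channel 0.41 and 180 genes. The ADSC-ovary and ADSC-iv arrays differed with an SD of 0.25 and in 22 genes in the WT channel, against 0.38 and 127 genes in the treated channel. Gene groups were described with 27 lists of markers and pathways. A list is said to stand apart when its median lay outside the middle 95% of the medians of 10000 random lists of equal size and brightness. If genes varied independently, chance alone would set about 1.35 of 27 lists apart in each comparison. Lists of genes that vary together can stand apart more often than that. Random lists ignore that genes of a pathway vary together, so this describes these libraries and does not extend to other animals.

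**Figure D1:**
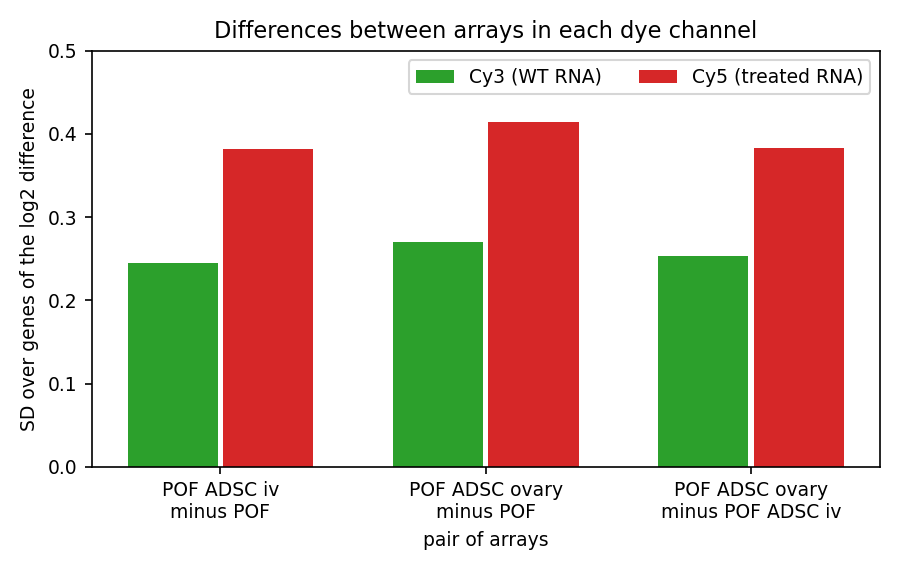
SD over 8946 genes of the log2 difference between arrays (y axis) for each of the 3 pairs of arrays (x axis), in the Cy3 channel with WT RNA (green bars) and in the Cy5 channel with RNA of treated ovaries (red bars). The WT bars reach 0.24, 0.27 and 0.25, and the treated bars 0.38, 0.41 and 0.38.

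The comparison of POF with WT addressed what cyclophosphamide left behind in the ovary. Immune genes were higher after chemotherapy. MHC genes, which encode antigen-presenting molecules, had a median of 1.42 with 12 of 12 above 0, led by H2-DMa (1.74), B2m (1.68), Psmb8 (1.60) and H2-K1 (1.56). Interferon-response genes had a median of 1.02, and 13 of 26 were at least 2-fold higher, among them the nucleic acid sensor Zbp1 (2.13), the immunity-related GTPases Irgm1 (1.77) and Iigp1 (1.72) and the immunoproteasome subunit Psmb8. Neutrophil genes had a median of 1.17 over 9 genes of 20 on the array, with S100a9 (2.21), Ltf (1.77), Ngp (1.43) and S100a8, which was above background in POF alone. None of these named genes was above background in WT. Such genes were measured only if the POF channel was above background, which favours values above 0.

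Macrophage genes were also higher, with a median of 0.54 and 25 of 26 above 0. Fcgr1 (1.58), Aif1 (1.46), Msr1 (1.25) and Fcer1g (1.24) were the farthest from 0. Inflammatory cytokine genes had a median of 0.56 over 13 genes. The interferon-induced chemokine Cxcl9 (1.68), Il1b (0.996) and Ccl3 (0.93) were higher, while the acute-phase gene Saa3 was lower (-1.55). Lymphocyte genes had a median of 0.33 over 8 genes with both directions present, from the cytotoxic granule genes Gzma (1.11) and Gzmb (0.78) and the killer cell receptor Klrd1 (0.66) to the immunoglobulin joining chain Jchain, which was above background in WT alone. Targets of p53, the factor activated by DNA damage, had a median of 0.18 over 20 genes. The cell cycle inhibitor Cdkn1a was higher (1.27) and Dcxr slightly so (0.50), and Sesn2 (-1.05) and Ccnd1 (-0.97) were lower.

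Markers of other tissues moved with these groups on the POF array. Erythroid genes had a median of 0.46 over 11 genes, with the globins Hba-a1 (1.85) and Hbb-b1 (1.80) and the heme synthesis gene Alas2 (1.62) each more than 2-fold higher. Oviduct and cilia genes had a median of 0.71 with 9 of 9 above 0, among them Dynlrb2 (1.41), Epcam (0.81), Wfdc2 (0.76) and the oviduct glycoprotein Ovgp1, which was above background in POF alone. Of the genes on the array, only 9 of 25 oviduct, 11 of 21 erythroid, 13 of 32 cytokine and 8 of 27 lymphocyte genes were measured. A gene not above background in WT was measured only if the POF channel was. The count above 0 can be partly set by that rule.

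Several groups of ovarian genes were lower after loess. Granulosa genes, which mark the somatic cells around the oocyte, had a median of -0.36 after loess and 0.09 after median centring, and stood below random lists under both. The members farthest from 0 were the oocyte growth ligand Kitl (-1.26), the nuclear receptor Nr5a2 (-0.998), the activin antagonist Fst (-0.87) and the BMP receptor Bmpr1b (-0.86). Endothelial and angiogenic genes had a median of -0.18 after loess and 0.13 after median centring, again below random lists under both, with Angpt1 (-1.29), Lyve1 (-0.68), Flt1 (-0.49, but 0.95 in the authors' values) and Eng (-0.41). Ovulation genes had a median of -0.27 after loess and 0.17 after median centring, with Vcan (-1.05), Pappa (-0.77), Rgcc (-0.49, positive after median centring) and Ereg (0.64). Cholesterol synthesis (-0.16, 0.41 after median centring), adipocyte (-0.17, 0.19 after median centring) and luteal genes (-0.14, 0.48 after median centring and 0.09 in the authors' values) were closer to 0. Their members farthest from 0 were Hsd17b7 (-0.97), Dhcr7 (-0.77), Fdps (-0.63) and Hmgcs1 (-0.57) for cholesterol synthesis, Cd36 (0.74), Lpl (-0.57), Agpat2 (-0.45) and Car3 (-0.36) for fat cells, and Hsd17b7, Lhcgr (-0.63), Star (-0.44, positive after median centring) and Cyp11a1 (0.41) for the corpus luteum.

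Oocyte genes did not stand apart, with a median of -0.02 over 25 genes, 12 above 0 and 13 below. The other lists that did not were theca and steroidogenic (-0.12), cell cycle (-0.06), extracellular matrix (-0.04), mesenchymal stem cell marker (-0.03), heat shock and unfolded protein (-0.03), housekeeping (-0.02), smooth muscle (0.02), growth factor (0.02), immediate early (0.06), oxidative and xenobiotic (0.07) and surface epithelium genes (0.17). The means of growth factor (-0.31), housekeeping (0.14), immediate early (-0.01) and mesenchymal marker genes (0.03) had the opposite sign to their medians.

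Among single bright genes, the largest log2 ratios in POF ovaries belonged to H2-Ea (2.40), the aldo-keto reductase Akr1b7 (2.02), Hba-a1, Hbb-b1, Irgm1, the macrophage gene Ms4a6d (1.76), H2-Q6 (1.71), B2m, H2-T3 (1.63), Psmb8, the guanylate-binding protein Gbp3 (1.59) and H2-K1. The lowest were the translation initiation factor Eif4g1 (-1.99), the RNA helicase Ddx6 (-1.60), the cell cycle inhibitor Cdkn1b (-1.59), Saa3, the meiotic recombination factor Psmc3ip (-1.54), the anaphase-promoting complex subunit Cdc27 (-1.39), Cnmd (-1.37), Cited1 (-1.29), Ccl21c (-1.26), Tbl1x (-1.21), the lymphoid chemokine Ccl21b (-1.17) and Pcyt1a (-1.17). For genes above background in the treated channel alone, Ovgp1 was at least 16.2-fold, S100a8 at least 8.10-fold and Plet1 at least 5.33-fold higher in POF. Above background in WT alone were IGHA, at least 3.23-fold lower in POF, Serpina6 at least 2.71-fold and Jchain at least 2.59-fold. The WT signal was not above background for Alas2, Cxcl9, Il1b, Ccl3, Gzma, Gzmb, Klrd1, Fcgr1, Msr1, S100a9, Ltf, Ngp, Dynlrb2 and Wfdc2, nor the POF signal for Angpt1, Vcan and Sesn2, so the size of their log2 ratios is uncertain.

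Of 9486 genes measured, 110 were at least 2-fold higher and 88 lower. Median centring in place of loess shifted the all-gene median by 0.32 and gave 264 higher and 30 lower, and the authors' values gave 571 and 224. Because the dyes were not exchanged, a gene-specific dye effect is part of each ratio to WT, and the granulosa, endothelial, ovulation, cholesterol, adipocyte and luteal medians are lower only relative to other genes of similar brightness. The lymphocyte, ovulation, cholesterol, adipocyte and luteal calls ended under at least 1 alternative. Over all alternatives the cytokine median ranged from 0.29 to 0.74, the macrophage median from 0.51 to 0.93, the neutrophil median from 0.52 to 2.51, the lymphocyte median from 0.05 to 0.58, the p53 median from 0.16 to 0.52 and the oviduct median from 0.34 to 0.92.

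**Figure D2:**
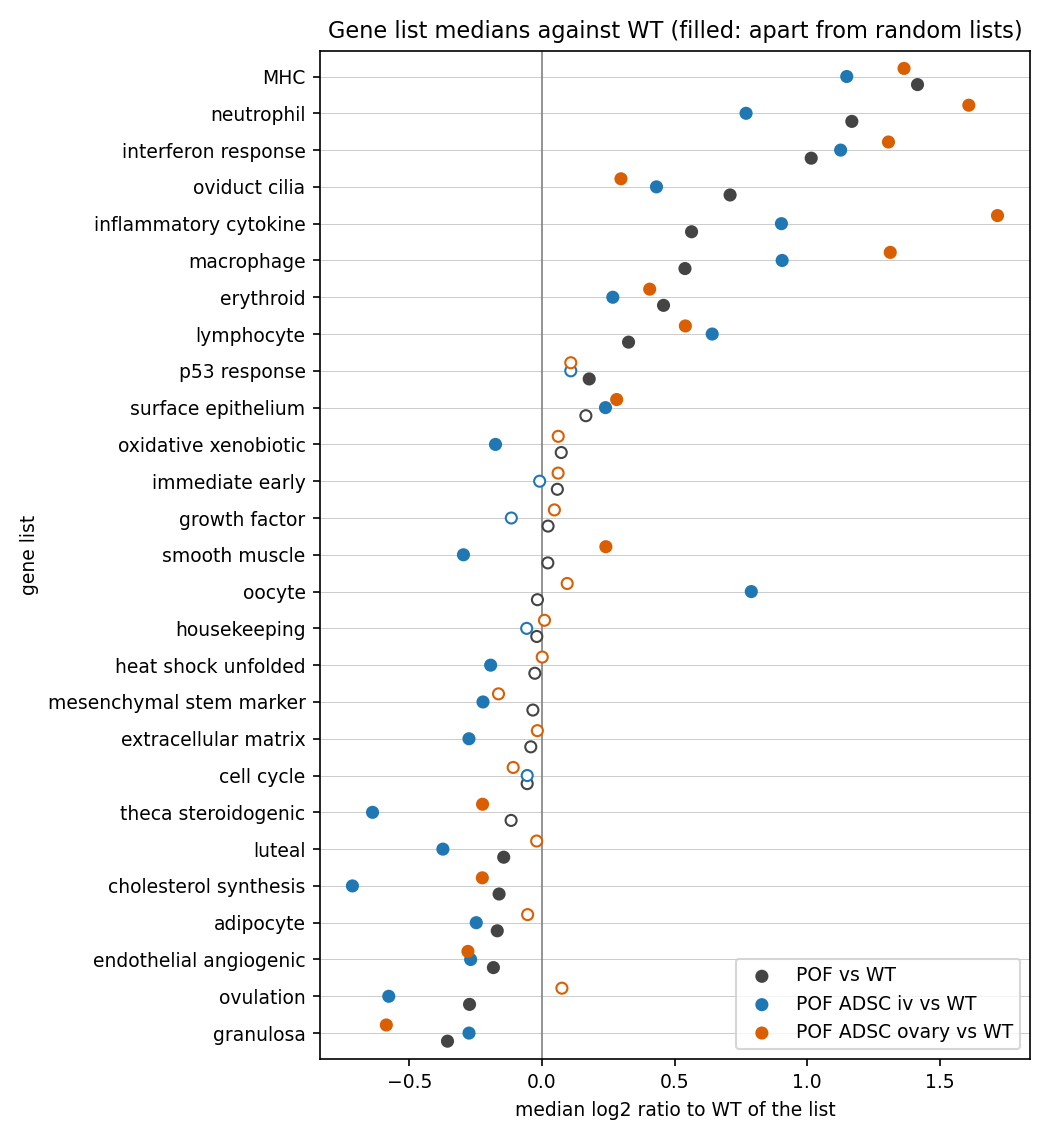
Median log2 ratio to WT (x axis) of each of 27 gene lists (y axis) on the POF array (dark grey), the ADSC-iv array (blue) and the ADSC-ovary array (orange); filled points stand apart from random lists. Immune lists lie to the right on all 3 arrays, oocyte genes are at -0.02, 0.79 and 0.10, and granulosa genes at -0.36, -0.28 and -0.59, where median centring turns the sign of the POF and ADSC-iv values (0.09 and 0.02).

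The ADSC-iv and POF arrays were compared to ask how ovaries with cells given into a vein differed from those with chemotherapy alone. Both arrays had the treated RNA in Cy5, so a gene-specific dye effect cancels in this difference. Oocyte genes were higher in ADSC-iv ovaries: the median was 0.77, 25 of 25 members were above 0 and 8 were at least 2-fold higher. Ooep (1.32) and Nlrp14 (1.27), which act in the early embryo from maternal stores, Oas1d (1.17) and the egg protease Astl (1.07, not above background in POF) led the list, and the growth factor Gdf9 was at 1.04, the transcription factor Figla at 1.06 and the zona pellucida genes Zp1, Zp2 and Zp3 at 0.64, 0.66 and 0.51. Granulosa genes did not stand apart (0.15, 14 of 21 above 0).

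Genes of sterol and steroid synthesis were lower. Cholesterol synthesis genes had a median of -0.54 with 21 of 22 below 0, from squalene epoxidase Sqle (-1.01), Tm7sf2 (-0.99), mevalonate kinase Mvk (-0.84) and Cyp51 (-0.78), while the regulator Srebf2 was at 0.29. For this list the treated channel differed by a median of -0.35 and the WT channel by 0.18, so a contribution from the WT side cannot be told apart. Theca and steroidogenic genes had a median of -0.47 with 16 of 18 below 0. Their treated channel differed by a median of -0.23 and the WT channel by 0.15, so part of this value may lie on the WT side. The androgen-producing enzyme Cyp17a1 was lowest (-1.91), followed by Fads2 (-1.11) and the electron donor Fdxr (-0.86), with the hedgehog target Gli1 at 0.96. Luteal genes had a median of -0.23, with the side-chain cleavage enzyme Cyp11a1 (-0.72), Sfrp4 (-0.65), Timp1 (-0.65) and Akr1c18 (0.64).

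Immune genes of 3 lists were higher still than in POF. Inflammatory cytokine genes had a median of 0.40 over 12 genes, with Saa3 (1.70), Ccl8 (1.27), Ccl9 (0.66) and Ccl5 (0.63). Macrophage genes had a median of 0.20, with Gpnmb (1.71), the lysozymes Lyz1 (1.34) and Lyz2 (1.21) and Ms4a7 (0.87), and lymphocyte genes 0.26 with Cd8a (0.93), Gzma (0.73), Klrd1 (0.39) and Lck (0.30). MHC (-0.13), interferon-response (0.08) and neutrophil genes (-0.06) did not stand apart. The erythroid list was at -0.60 beside these groups, with Alas2 (-1.36), Hba-a1 (-1.21) and Hbb-b1 (-0.96), and the oviduct list at -0.28, with Ovgp1 (-3.90), Dynlrb2 (-0.72), Epcam (-0.54) and Rsph1 (-0.43). For erythroid genes the treated channel differed by a median of -0.40 and the WT channel by 0.18, so part of their value may lie on the WT side. Smooth muscle genes were at -0.38, with the filament gene Des (-1.29), Myh11 (-0.59), Kcnmb1 (-0.59) and Actg2 (-0.55). Extracellular matrix genes had a median of -0.17, with Fn1 (-0.85), Timp1, Col1a1 (-0.64) and Dcn (0.52).

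The single bright genes with the largest positive differences were the cystatin Cst8 (2.31), Gpnmb, Saa3, the small nucleolar RNA U3 (1.35), Lyz1, Ooep, Fbxw21 (1.28), Nlrp14, S100a4 (1.21), Ccl21b (1.20), Oas1d and the matrix protein Efemp1 (1.07). Saa3 and Ccl21b were low on the POF array and close to WT on the ADSC-iv array (0.16 and 0.03 against WT). The most negative were Cyp17a1, the alcohol dehydrogenase Adh1 (-1.24), Hba-a1, Fads2, Glo1 (-1.08), Abhd3 (-1.06), Sqle, Tm7sf2, Slc3a2 (-0.98), Pld3 (-0.97), Hbb-b1 and Akr1b7 (-0.95).

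Of 9168 genes, 47 were at least 2-fold higher in ADSC-iv than in POF and 32 lower. With median centring, which moved the all-gene median by -0.11, the counts were 37 and 67, and the authors' values gave 239 and 341, so neither direction predominates under every scaling. The luteal call ended under 9 of 13 alternatives and the lymphocyte call under 5 of 11, and single alternatives ended the macrophage (0.09 in the authors' values) and smooth muscle calls (-0.15 with no filter on dim genes). Over all alternatives the cytokine median ranged from 0.21 to 0.66, the macrophage median from 0.09 to 0.48, the erythroid median from -0.90 to -0.24, the oviduct median from -0.53 to -0.23, the luteal median from -0.37 to -0.18 and the matrix median from -0.30 to -0.16.

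The ADSC-ovary and POF arrays were compared to ask how ovaries injected with the cells differed from those with chemotherapy alone. Inflammatory genes were far higher in the injected ovaries. Cytokine genes had a median of 1.23 with 12 of 12 above 0 and 8 at least 2-fold higher: Cxcl9 (2.86) and the monocyte and T cell attractants Ccl8 (2.55) and Ccl5 (2.36) had the largest values, followed by Saa3 (2.09). Saa3 was low on the POF array (-1.55 against WT) and at 0.54 against WT on the ADSC-ovary array, so much of its difference lies in the low POF value. The WT signal of Cxcl9 was not above background on the POF array. Neutrophil genes had a median of 0.86 over 8 genes, with Chil3 (1.25, but -0.33 in the authors' values), S100a9 (1.13), Lcn2 (0.94) and Hp (0.94). Macrophage genes were at 0.75 with 23 of 24 above 0, led by Lyz2 (1.08), Fcer1g (1.01), Aif1 (0.98) and Fcgr3 (0.97). Lymphocyte genes were at 0.51, with Gzmb (1.57), Gzma (1.25), Klrd1 (0.78) and Cd8a (0.62), and interferon-response genes at 0.44, with Gbp2 (1.51), Zbp1 (1.16), Gbp3 (0.88) and Ifit2 (0.80). For the lymphocyte list the treated channel differed by a median of 0.25 and the WT channel by -0.23. A contribution from the WT side therefore cannot be told apart from a change in the injected ovaries.

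Follicle genes were not higher in the injected ovaries. Oocyte genes had a median of 0.06 over 24 genes and did not stand apart, and cholesterol synthesis genes were at -0.01. Granulosa genes had a median of -0.23 with 15 of 21 below 0, from the estradiol-producing enzyme Hsd17b1 (-0.78), Nap1l5 (-0.74) and the inhibin subunit Inha (-0.70), with Kitl at 0.73. Theca and steroidogenic genes were at -0.26, with the retinal dehydrogenase Aldh1a1 (-1.003), Cyp17a1 (-0.72), Fdxr (-0.59) and the cholesterol carrier Star (0.72). Targets of p53 were at -0.19, where the stress gene Ddit4 (-1.18) and Aen (-0.58) were lower and the death receptor Fas (1.14) and Ccnd1 (0.75) higher. For p53 targets the treated channel differed by a median of only -0.04 and the WT channel by 0.04, so a fall in the injected ovaries is not shown. Beside these groups the oviduct list was at -0.44, with Ovgp1 (-3.83), Epcam (-0.74), Tppp3 (-0.70) and Wfdc2 (-0.55), and the erythroid list at -0.15 and not apart. For oviduct genes the treated channel differed by a median of only -0.13 and the WT channel by 0.03, so the size of that difference is uncertain. Smooth muscle genes were at 0.22, with Cald1 (0.47), Rgs5 (0.45), Lmod1 (0.37) and Tpm1 (-0.51). Their treated channel differed by a median of only 0.08 and the WT channel by -0.19, so much of this value may lie on the WT side.

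The single bright genes with the largest positive differences were Saa3, H2-Ea (1.59), Gbp2, S100a4 (1.42), Efemp1 (1.36), Ms4a6d (1.27), the surface antigen Ly6a (1.14), the MHC class II chaperone Cd74 (1.10), Lyz2, Ccl21b (1.02), Fcer1g and Aif1. Like Saa3, Ccl21b was low on the POF array (-1.17 against WT), and it was at -0.15 against WT on the ADSC-ovary array. The most negative were Ddit4, Gas6 (-1.14), Aldh1a1, Dhrs1 (-0.99), Grn (-0.99), the cathepsin Ctsf (-0.97), the cold-inducible Cirbp (-0.93), Crtap (-0.92), Mfge8 (-0.90), Nop53 (-0.90), Wsb2 (-0.90) and Adh1 (-0.89).

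Of 9077 genes, 59 were at least 2-fold higher in ADSC-ovary than in POF and 14 lower. With median centring, which moved the all-gene median by -0.14, the counts were 48 and 68, and the authors' values gave 310 and 313. The p53 and smooth muscle calls each ended under 4 of 13 alternatives, the granulosa call in the authors' values (-0.20), and the theca and lymphocyte calls with no filter on dim genes (-0.13 and 0.09). Without that filter the cytokine median was 0.51, the neutrophil median 0.38 and the oviduct median -0.26, and over all alternatives the cytokine median ranged from 0.51 to 1.58, the lymphocyte median from 0.09 to 0.77 and the p53 median from -0.28 to -0.05.

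**Figure D3:**
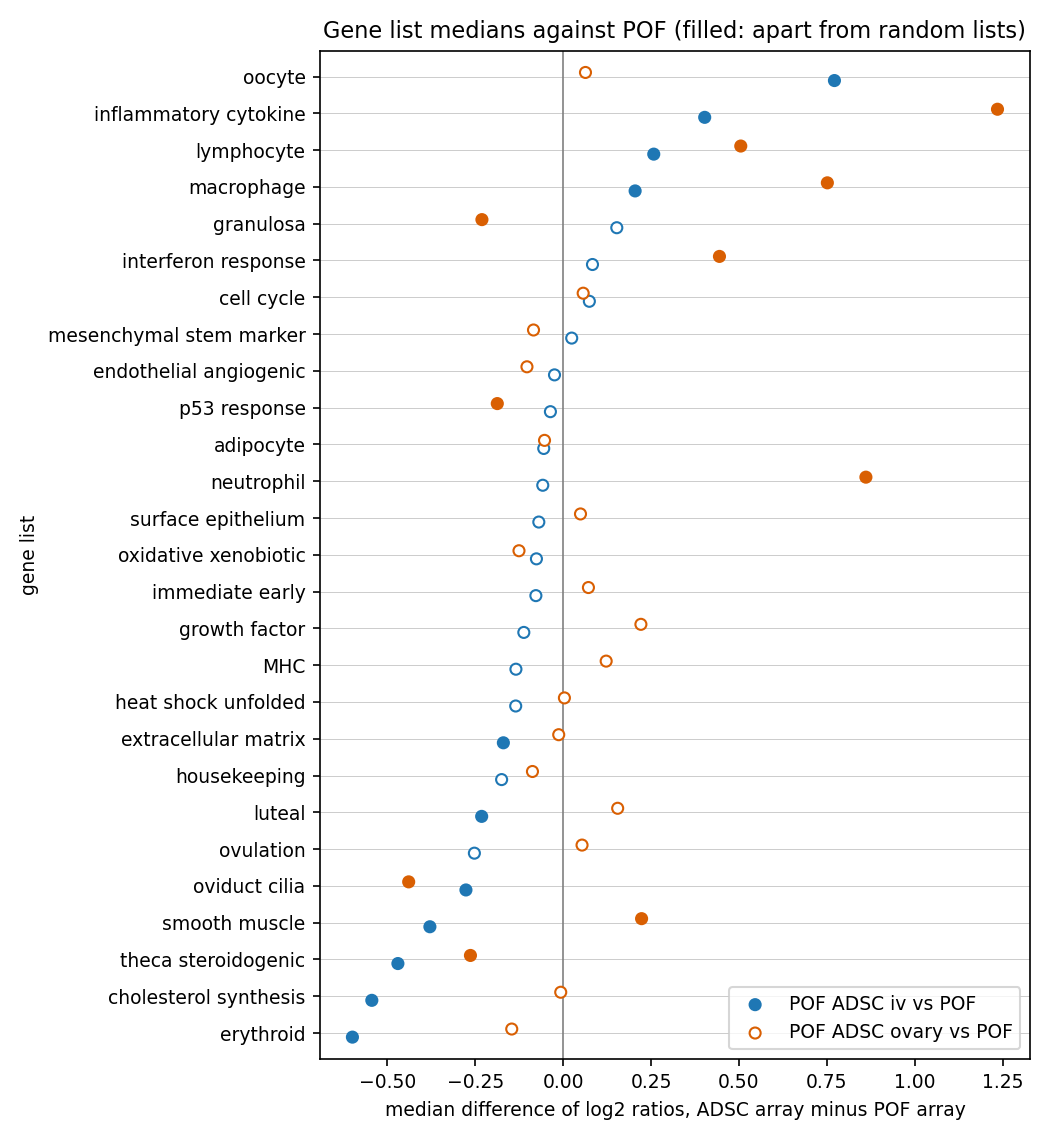
Median difference of log2 ratios from the POF array (x axis) of each of 27 gene lists (y axis) on the ADSC-iv array (blue) and the ADSC-ovary array (orange); filled points stand apart from random lists. Oocyte genes are at 0.77 and 0.06, cholesterol synthesis genes at -0.54 and -0.01, and inflammatory cytokine genes at 0.40 and 1.23.

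Genes above background on 1 array of a pair and not on the other were read with care. For all 12 of the largest such differences between an ADSC array and the POF array, the WT channel of the same spots differed in the same direction, by 2.22 to 4.91 log2 units. No fold is given for them. For Ovgp1, Cd8a and Gzma the WT signal was not above background on either array of the comparisons with POF, so their differences rest on the treated channels. The same holds in the comparison of ADSC-ovary with POF for Gzmb, Klrd1, Chil3, S100a9, Lcn2, Ifit2, Fas, Lmod1 and Wfdc2, and in that of ADSC-iv with POF for Dynlrb2. The WT signal was not above background on 1 of the arrays for Cxcl9 (ADSC-ovary with POF) and for Alas2, Klrd1 and Gli1 (ADSC-iv with POF), and the size of their differences is uncertain.

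The ADSC-ovary and ADSC-iv arrays were set against each other to compare the routes of delivery. Oocyte genes were lower after injection into the ovary than into a vein (-0.70, 24 of 25 below 0), and so were granulosa (-0.41, 20 of 23 below 0) and endothelial genes (-0.13). Cytokine (1.01), neutrophil (1.01), MHC (0.42), macrophage (0.30) and interferon-response genes (0.28) were higher. Smooth muscle (0.50), cholesterol synthesis (0.44), luteal (0.31), theca (0.24), extracellular matrix (0.23), ovulation (0.37), growth factor (0.30) and adipocyte genes (0.25) were higher as well, and so were erythroid genes (0.42). For theca genes the treated channel differed by a median of only 0.08 and the WT channel by -0.20. For luteal genes these were 0.11 and -0.08, so a contribution from the WT side cannot be told apart for either list. Among single bright genes H2-Ea (1.76), Emb (1.53), Hbb-b1 (1.41), Sectm1a (1.38) and Gbp2 (1.36) were the highest and Comp (-1.34), Gpnmb (-1.33), Serpina3a (-1.29), the monoamine transporter Slc18a2 (-1.24) and Prss23 (-1.19) the lowest. Of 9457 genes, 60 were at least 2-fold higher and 31 lower, and 60 and 48 with median centring. The endothelial call ended under 8 of 13 alternatives, the growth factor call under 4, the ovulation and adipocyte calls under 2 each and the MHC call without the spots that carried a flag of -100 (0.15). Over all alternatives the cytokine median ranged from 0.37 to 1.32, the macrophage median from 0.19 to 0.36, the erythroid median from 0.20 to 0.65, the ovulation median from 0.09 to 0.56 and the adipocyte median from 0.06 to 0.28. The growth factor median turned to -0.04 with no filter on dim genes.

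**Figure D4:**
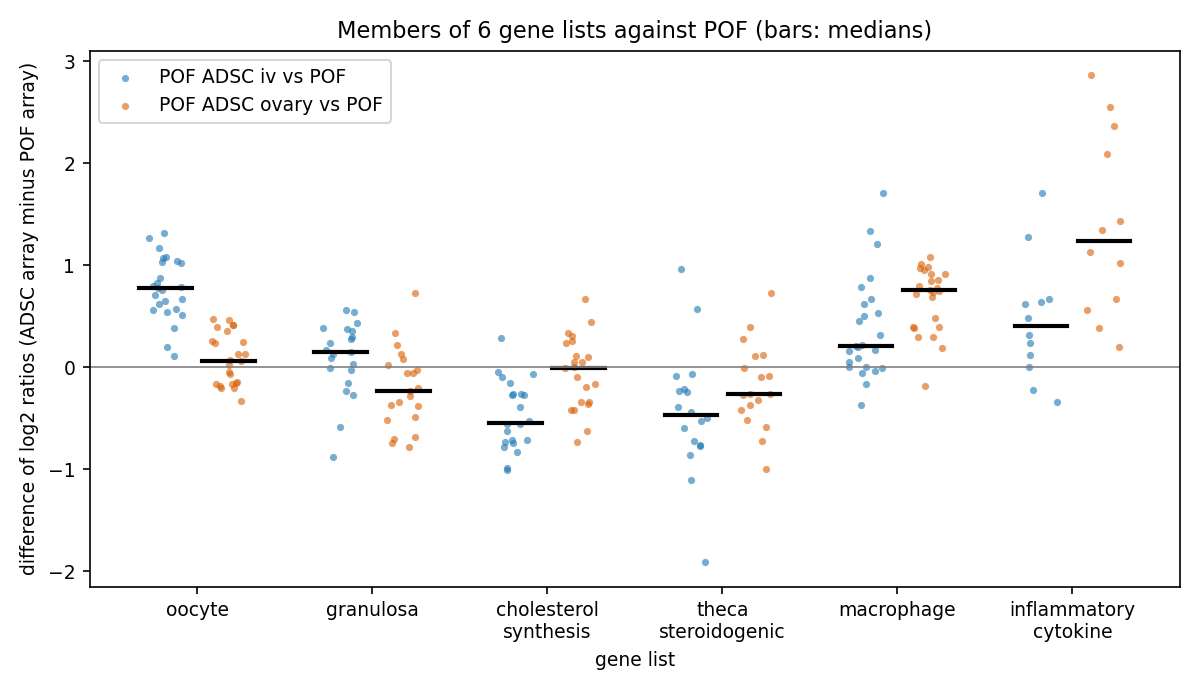
Difference of log2 ratios from the POF array (y axis) for each measured member (points) of 6 gene lists (x axis), on the ADSC-iv array (blue) and the ADSC-ovary array (orange), with bars at the medians. All 25 oocyte genes lie above 0 on the ADSC-iv array, while on the ADSC-ovary array 14 of 24 do, and all 12 cytokine genes lie above 0 on the ADSC-ovary array.

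Against WT, ADSC-iv ovaries had higher interferon-response (1.13), MHC (1.15), macrophage (0.91), cytokine (0.90), oocyte (0.79, 29 of 30 above 0), neutrophil (0.77) and lymphocyte genes (0.64). Oviduct (0.43), erythroid (0.27) and surface epithelium genes (0.24) were higher too. Only 9 of 25 oviduct, 9 of 20 neutrophil and 16 of 32 cytokine genes on the array were measured. For genes not above background in WT, the filter favours values above 0. Cholesterol synthesis (-0.71), theca (-0.64), ovulation (-0.58), endothelial (-0.27) and adipocyte genes (-0.25) were lower. Luteal (-0.37), smooth muscle (-0.30), granulosa (-0.28), extracellular matrix (-0.28), mesenchymal marker (-0.22), heat shock (-0.19) and oxidative genes (-0.18) were lower after loess, and after median centring their medians were 0.17, 0.03, 0.02, 0.02, 0.05, 0.17 and 0.18. The highest single bright genes were Zbp1 (2.51), H2-Ea (2.22), Rmcs2 (2.19), Aif1 (2.13) and the leukocyte antigen Cd52 (2.12), and the lowest Pcyt1a (-1.59), the BMP receptor Bmpr2 (-1.56), Atp12a (-1.39), Eif4g1 (-1.32) and Cyp17a1 (-1.31). Of 10156 genes, 203 were at least 2-fold higher and 56 lower, and 433 and 28 with median centring, which shifted the all-gene median by 0.17. The oviduct, erythroid, surface epithelium, adipocyte, luteal, smooth muscle, mesenchymal, heat shock and oxidative calls ended under at least 1 alternative. The medians ranged from 0.25 to 1.13 for cytokine, 0.34 to 2.17 for neutrophil, 0.23 to 1.11 for lymphocyte and 0.81 to 1.44 for macrophage genes. They ranged from 0.12 to 0.55 for oviduct, 0.11 to 0.46 for erythroid and 0.19 to 0.38 for surface epithelium genes. For lower lists they ranged from -0.84 to -0.39 for cholesterol, -0.72 to -0.23 for theca, -0.75 to -0.28 for ovulation, -0.37 to -0.07 for endothelial and -0.30 to -0.13 for adipocyte genes.

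ADSC-ovary ovaries had higher cytokine (1.72, 19 of 19 above 0), neutrophil (1.61), MHC (1.37), macrophage (1.31), interferon-response (1.31) and lymphocyte genes (0.54) than WT. Of the genes on the array, 19 of 32 cytokine and 10 of 20 neutrophil genes were measured. A gene not above background in WT was measured only if the treated channel was, which favours values above 0. The count above 0 and the rank among random lists can be partly set by that rule. Erythroid (0.41), oviduct (0.30), surface epithelium (0.28) and smooth muscle genes (0.24) were higher too. Granulosa genes (-0.59, 21 of 23 below 0) and endothelial genes (-0.28) were lower, and cholesterol synthesis (-0.22) and theca genes (-0.22) were lower after loess but at 0.10 and 0.11 after median centring. Oocyte genes did not stand apart (0.10). The highest single bright genes were Cxcl9 (4.54), H2-Ea (3.98), Serpina3g (3.41), Ccl8 (3.37) and Zbp1 (3.29). The lowest were the activin subunit Inhba (-1.44), Ddx6 (-1.40), Fst (-1.39), Eif4g1 (-1.38) and Gas6 (-1.16). Of 9942 genes, 266 were at least 2-fold higher and 35 lower. Median centring shifted the all-gene median by 0.15 and gave 442 and 22, and plain background subtraction gave 576 and 178. The erythroid, oviduct, surface epithelium, smooth muscle and theca calls ended under at least 1 alternative. The medians ranged from 0.52 to 2.501 for cytokine, 1.12 to 2.99 for neutrophil and 0.36 to 1.44 for lymphocyte genes. They ranged from 0.21 to 0.86 for erythroid, 0.18 to 0.42 for oviduct, 0.19 to 0.44 for smooth muscle, -0.68 to -0.35 for granulosa and -0.36 to -0.09 for endothelial genes.

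Whether the ovaries of treated animals lay nearer to WT than those with chemotherapy alone was asked gene by gene and list by list. Of the 98 genes at least 2-fold higher in POF than in WT and measured on all arrays, 57 were closer to WT on the ADSC-iv array (58.2%) and 28 on the ADSC-ovary array (28.6%). Of the 86 lower genes, 72 (83.7%) and 78 (90.7%) were closer. Genes picked on 1 array move toward WT on another by chance alone, so the reverse reading is given beside these shares. The reverse shares may also include genes that differ between the groups, and the numbers of genes picked are unlike. They are therefore no measure of chance alone, and no change toward WT is concluded from the shares. Of 179 genes higher on the ADSC-iv array, 148 were closer to WT in POF (82.7%), and of 218 higher on the ADSC-ovary array 200 were (91.7%). For lower genes the reverse shares were 38 of 51 (74.5%) and 26 of 32 (81.2%). The shares of higher genes lay below their reverse shares with both routes, and the shares of lower genes above theirs. With median centring the shares of higher genes (70.0% and 47.4%) stayed below their reverse shares, but those of lower genes (78.6% with each route) lay below theirs too, with a reverse share of 87.5% for ADSC-iv. The list medians against WT are over the genes measured on each array, which are not the same genes. On the POF, ADSC-iv and ADSC-ovary arrays there were 13, 16 and 19 cytokine genes and 8, 10 and 13 lymphocyte genes. Of the 15 lists apart in POF, 4 had medians nearer to 0 with both routes. Oviduct genes stood at 0.71 in POF, 0.43 in ADSC-iv and 0.30 in ADSC-ovary, erythroid genes at 0.46, 0.27 and 0.41 and p53 targets at 0.18, 0.11 and 0.11. The differences from POF of erythroid genes in ADSC-ovary (-0.15) and of p53 targets in ADSC-iv (-0.04) did not stand apart from random lists. In ADSC-ovary the treated channel differed from POF by a median of only -0.13 for oviduct genes and -0.04 for p53 targets. MHC genes were the other list with nearer medians, at 1.42, 1.15 and 1.37. However, the medians of their differences from POF were -0.13 in ADSC-iv and 0.12 in ADSC-ovary, and neither stood apart. In ADSC-ovary 6 of 12 MHC genes were higher than in POF, so no move toward WT is read there. Neutrophil genes (1.17, 0.77 and 1.61) and granulosa genes (-0.36, -0.28 and -0.59, the former pair 0.09 and 0.02 after median centring) had nearer medians in ADSC-iv alone. Their differences from POF in ADSC-iv, -0.06 for neutrophil and 0.15 for granulosa genes, did not stand apart. Cytokine (0.56, 0.90 and 1.72), interferon-response (1.02, 1.13 and 1.31), macrophage (0.54, 0.91 and 1.31) and lymphocyte genes (0.33, 0.64 and 0.54) had medians farther from 0 with both routes. The difference of interferon-response genes from POF in ADSC-iv (0.08) did not stand apart. Lymphocyte genes compared directly between ADSC-ovary and ADSC-iv were at 0.15, also not apart. After loess, luteal (-0.14, -0.37 and -0.02) and ovulation genes (-0.27, -0.58 and 0.08) had nearer medians in ADSC-ovary alone. Their differences from POF in ADSC-ovary, 0.16 for luteal and 0.05 for ovulation genes, did not stand apart either. Adipocyte genes stood at -0.17, -0.25 and -0.05, and their difference from POF in ADSC-ovary was -0.05 but 0.11 with median centring and 0.37 in the authors' values. Cholesterol synthesis genes stood at -0.16, -0.71 and -0.22 and endothelial genes at -0.18, -0.27 and -0.28. Median centring turned the POF medians of these 5 lists positive.

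The ratios of the 3 arrays are all to WT RNA, and if that RNA was the same on each array, this alone makes them correlate. Across the 8946 genes, which are not independent replicates, Pearson's r was 0.592 between POF and ADSC-iv, 0.645 between POF and ADSC-ovary and 0.708 between the ADSC arrays, against 0.487, 0.496 and 0.496 for simulated unchanged groups with a shared reference. The covariances were 0.0805, 0.0956 and 0.117 against simulated 0.0375, 0.0372 and 0.0462. Genes at least 2-fold higher on both arrays of a pair numbered 72, 88 and 120, where independent lists would share 1.96, 2.39 and 4.36, and genes lower on both numbered 27, 14 and 16 against 0.490, 0.308 and 0.182. Simulated unchanged groups with a shared reference had 0.02, 0.06 and 0.34 higher genes in common and 0.04, 0.02 and 0.28 lower genes. Their spread was set from the median absolute deviation of the real ratios within brightness bins, which leaves out the tails of the real values. Over all measured genes that kind of spread was 0.25, 0.31 and 0.31 on the POF, ADSC-iv and ADSC-ovary arrays, against SDs of 0.35, 0.39 and 0.43. Few simulated genes could thus reach 2-fold, and the simulated covariances are partly low by this setting. Part of the excess over independent lists may come from the shared WT RNA, and the simulated counts cannot measure how much. A gene-specific dye effect would repeat on all 3 arrays, because the dyes were not exchanged. It cannot be told apart here from changes in expression common to the treated groups.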

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

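The tests of more blood, more macrophages and fewer steroid-producing cells were chosen only after the results they measure had been seen, and the 3 patterns were picked after the list medians were known.

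Oocyte genes were higher in ADSC-iv than in POF ovaries, with a median of 0.77 over 25 genes, and the pattern was present in the treated channel (0.64). An uneven signal across the slide is argued against by the median of 0.83 ± 0.06 (bootstrap spread over genes) with loess in each print block, noise of dim spots by the median of 0.77 ± 0.06 among the 21 members above background in both channels of both arrays, and a difference on the WT side by a Cy3 difference of only -0.12 ± 0.04. More oocytes relative to other cells in the tissue taken would raise the members together, and 100% of the 25 lay above 0, but this restates the pattern and decides nothing. A larger oocyte share and higher expression per oocyte cannot be told apart for these genes, because the arrays measured whole tissue. Chance differences between the animals sampled, or in how much other tissue was taken along, stay open with 1 array per group, and the oviduct list was at -0.28 in the same comparison.

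Inflammatory cytokine genes were higher in ADSC-ovary than in POF ovaries, with a median of 1.23 over 12 genes and 1.15 in the treated channel. A difference on the WT side is argued against by a Cy3 difference of -0.02 ± 0.12. For more blood in the tissue taken, the erythroid median was -0.15 ± 0.15, with 3 members above 0 and 7 below. The limit for that test was written after this value was known, so the test decides nothing about blood. Macrophage genes had a median of 0.75 ± 0.07 over 24 genes, which lies between the cytokine median and 0.5 of it. More macrophages and a higher output per cell cannot be told apart for these genes, because the arrays measured whole tissue. An effect of the injected cells, of the injection itself or of the animals sampled could each give this pattern, and the design has no ovary injected without cells to separate them.

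Cholesterol synthesis genes were lower in ADSC-iv than in POF ovaries, with a median of -0.54 over 22 genes. An uneven signal across the slide is argued against by the median of -0.52 ± 0.14 with loess in each print block. The WT channel of the same genes was higher on the ADSC-iv array by 0.18 ± 0.05, beside a treated-channel difference of -0.35, so a contribution from the WT side cannot be told apart from a change in the treated ovaries: the value lies between the limits of 0.15 and 0.3 set for that test. Fewer steroid-producing cells in the tissue taken cannot be excluded either, since theca and steroidogenic genes without those shared with the list had a median of -0.44 ± 0.15 over 17 genes, too close to the limit of -0.4 for its spread. The WT channel of the full theca list was itself higher on the ADSC-iv array, by a median of 0.15. The pattern is not called biological here.

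Smooth muscle genes had medians of opposite sign with the 2 routes, at -0.38 in ADSC-iv and 0.22 in ADSC-ovary against POF. In ADSC-iv the treated channel differed by -0.34 and the WT channel by -0.02. In ADSC-ovary the treated channel differed by only 0.08 and the WT channel by -0.19, so a rise in the injected ovaries is not shown. That call also ended under 4 of 13 alternatives. The median of 0.50 in ADSC-ovary against ADSC-iv stood apart from random lists. No difference was tested between animals. Spots of 50% DMSO, which were not used in any comparison, gave a signal above background in 48, 48 and 45 of 48 cases on the POF, ADSC-iv and ADSC-ovary arrays, while 0 of 768 blank spots did. Probes without a name, also outside the comparisons, were above background in 1821, 2080 and 2048 of 7528 cases on the same arrays, with 27, 45 and 47 of them at least 2-fold higher and 22, 19 and 10 lower than WT.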

How the results depend on the processing

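The average over a gene's probes above background was chosen after the data had been seen. No paired analysis was possible because each group had 1 array and the groups share 1 replicate number. The self-test shows what signal over background limits: in the simulated comparison of ADSC-iv with WT, 53 of 54 brighter genes with a true log2 fold of 1.5 passed 2-fold, and 19 of 41 among the dimmer. Of the 89 list medians that stood apart over the 6 comparisons, 56 did so under every alternative that gave a value. These include the oocyte, cholesterol, theca and cytokine medians in ADSC-iv vs POF and the cytokine, neutrophil, macrophage and interferon medians in ADSC-ovary vs POF. Of 2521 alternative values of 217 named gene values, 2290 moved by less than the largest SD between WT channels (0.27), 226 moved farther with the sign kept and 5 turned sign. The 2290 include 217 values with no filter and 174 with the filter on both channels, which keep or drop a gene and cannot move its value. They also include 217 values of the average over probes above background, which cannot move a gene with 1 probe. These say nothing about stability. Where a filter or probe rule left under 5 measured genes, a list has no value. The alternatives below are given only where a count left 1.5 times its main value, a list crossed the limits of random lists or a sign turned, and the cause was not tested. The 1.5-fold threshold, the filters and the omission of spots change counts by their construction.

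Plain background subtraction gave 376 higher and 246 lower in POF vs WT, 519 higher and 207 lower in ADSC-iv vs WT and 576 higher and 178 lower in ADSC-ovary vs WT. Its counts were 189 higher and 225 lower in ADSC-iv vs POF, 230 higher and 190 lower in ADSC-ovary vs POF and 260 higher and 182 lower in ADSC-ovary vs ADSC-iv. Under plain background subtraction, lymphocyte (0.51) in POF vs WT, heat shock (-0.21) and mesenchymal (-0.24) in ADSC-iv vs WT, surface epithelium (0.29) in ADSC-ovary vs WT and luteal (-0.24) and lymphocyte (0.24) in ADSC-iv vs POF no longer stood apart. Endothelial (-0.19) in ADSC-ovary vs POF newly stood apart. Median centring gave 264 higher and 30 lower in POF vs WT, 433 higher and 28 lower in ADSC-iv vs WT and 442 higher and 22 lower in ADSC-ovary vs WT, then 67 lower in ADSC-iv vs POF, 68 lower in ADSC-ovary vs POF and 48 lower in ADSC-ovary vs ADSC-iv. Under median centring, adipocyte (0.19), cholesterol (0.41), luteal (0.48) and ovulation (0.17) in POF vs WT, erythroid (0.46), heat shock (0.17), mesenchymal (0.054), oxidative (0.18), smooth muscle (0.033) and surface epithelium (0.30) in ADSC-iv vs WT, oviduct (0.32) and smooth muscle (0.44) in ADSC-ovary vs WT and p53 (-0.28) in ADSC-ovary vs POF no longer stood apart. Adipocyte (0.11) in ADSC-ovary vs POF turned sign. Endothelial (0.13) and granulosa (0.09) in POF vs WT turned positive but still stood below random lists. So did matrix (0.02), granulosa (0.02) and luteal (0.17) in ADSC-iv vs WT and cholesterol (0.10) and theca (0.11) in ADSC-ovary vs WT. Cell cycle (0.26) and oxidative (0.59) in POF vs WT, cell cycle (0.089) in ADSC-iv vs WT, ovulation (-0.40) in ADSC-iv vs POF, MHC (0.13) in ADSC-ovary vs POF and heat shock (0.22) in ADSC-ovary vs ADSC-iv newly stood apart. Star (0.058) and Rgcc (0.052) then turned positive in POF vs WT. The shares of genes closer to WT became 70.0% and 47.4% for genes higher in POF read on the ADSC-iv and ADSC-ovary arrays, 78.6% for genes lower in POF read on ADSC-ovary and 87.5% for genes lower on ADSC-iv read in POF. The authors' values gave 571 higher and 224 lower in POF vs WT, 664 higher and 196 lower in ADSC-iv vs WT and 728 higher and 153 lower in ADSC-ovary vs WT, then 239 higher and 341 lower in ADSC-iv vs POF, 310 higher and 313 lower in ADSC-ovary vs POF and 379 higher and 265 lower in ADSC-ovary vs ADSC-iv. Under the authors' values, adipocyte (-0.094), cholesterol (-0.050), luteal (0.085) and lymphocyte (0.58) in POF vs WT, adipocyte (-0.18), mesenchymal (-0.20), oviduct (0.39), oxidative (-0.15) and surface epithelium (0.24) in ADSC-iv vs WT and oviduct (0.35) and theca (-0.0025) in ADSC-ovary vs WT no longer stood apart. Luteal (-0.25), lymphocyte (0.23) and macrophage (0.091) in ADSC-iv vs POF, granulosa (-0.20) and p53 (-0.24) in ADSC-ovary vs POF and endothelial (-0.14) and growth factor (0.27) in ADSC-ovary vs ADSC-iv did not either. Adipocyte (0.37) in ADSC-ovary vs POF turned sign. Matrix (-0.058) in POF vs WT, cell cycle (-0.18) in ADSC-ovary vs WT, MHC (-0.30) in ADSC-iv vs POF, oxidative (-0.18) in ADSC-ovary vs POF and housekeeping (0.17) in ADSC-ovary vs ADSC-iv newly stood apart. Single genes of opposite sign were Flt1 in POF vs WT (0.95) and Chil3 in ADSC-ovary vs POF (-0.33). The filter on both channels gave 69 higher in POF vs WT, 166 higher in ADSC-ovary vs WT and 37 higher and 8 lower in ADSC-ovary vs POF. Under the filter on both channels, mesenchymal (-0.23) in ADSC-iv vs WT, erythroid (0.21) in ADSC-ovary vs WT, luteal (-0.23) in ADSC-iv vs POF and endothelial (-0.13), growth factor (0.12) and ovulation (0.093) in ADSC-ovary vs ADSC-iv no longer stood apart. Surface epithelium (0.17) in POF vs WT and oxidative (-0.14) in ADSC-ovary vs POF newly stood apart. The 1.5-fold threshold gave 371 higher and 389 lower in POF vs WT, 681 higher and 392 lower in ADSC-iv vs WT and 634 higher and 362 lower in ADSC-ovary vs WT, then 379 higher and 305 lower in ADSC-iv vs POF, 351 higher and 269 lower in ADSC-ovary vs POF and 294 higher and 274 lower in ADSC-ovary vs ADSC-iv. The brightest probe gave 135 lower in POF vs WT. Under the brightest probe, lymphocyte (0.33) in POF vs WT, heat shock (-0.13) and oxidative (-0.15) in ADSC-iv vs WT and luteal (-0.23) and lymphocyte (0.20) in ADSC-iv vs POF no longer stood apart. P53 (-0.066) in ADSC-ovary vs POF and endothelial (-0.11) in ADSC-ovary vs ADSC-iv did not either. Adipocyte (-0.30) in ADSC-ovary vs WT and housekeeping (-0.24) and ovulation (-0.32) in ADSC-iv vs POF newly stood apart. No filter on dim genes gave 134 higher and 110 lower in ADSC-iv vs POF, 177 higher and 100 lower in ADSC-ovary vs POF and 156 higher and 95 lower in ADSC-ovary vs ADSC-iv, then 92 lower in ADSC-iv vs WT and 79 lower in ADSC-ovary vs WT. Under no filter on dim genes, adipocyte (-0.010), luteal (-0.076) and lymphocyte (0.047) in POF vs WT, erythroid (0.11), heat shock (-0.16), mesenchymal (-0.15), oviduct (0.12) and oxidative (-0.084) in ADSC-iv vs WT and luteal (-0.18) and smooth muscle (-0.15) in ADSC-iv vs POF no longer stood apart. Lymphocyte (0.090) and theca (-0.13) in ADSC-ovary vs POF and adipocyte (0.056) in ADSC-ovary vs ADSC-iv did not either. Ovulation (0.071) in POF vs WT and growth factor (-0.042) in ADSC-ovary vs ADSC-iv turned sign. Oxidative (0.11) in POF vs WT, p53 (0.18) in ADSC-ovary vs WT and granulosa (0.17) and ovulation (-0.24) in ADSC-iv vs POF newly stood apart. No background correction gave 9 lower in ADSC-ovary vs POF. Under no background correction, adipocyte (-0.12) in POF vs WT, surface epithelium (0.19) in ADSC-iv vs WT and oviduct (0.18) in ADSC-ovary vs WT no longer stood apart. P53 (-0.045) and smooth muscle (0.15) in ADSC-ovary vs POF and adipocyte (0.11) and endothelial (-0.11) in ADSC-ovary vs ADSC-iv did not either. Cell cycle (-0.085) and theca (-0.13) in POF vs WT, cell cycle (-0.11) in ADSC-ovary vs WT, ovulation (-0.31) in ADSC-iv vs POF and immediate early (0.18) in ADSC-ovary vs ADSC-iv newly stood apart. Lmod1 in ADSC-ovary vs POF was then at -0.0091. The normexp offset of 16 gave 26 lower in ADSC-ovary vs POF. Under the normexp offset of 16, luteal (-0.24) and lymphocyte (0.25) in ADSC-iv vs POF no longer stood apart. Leaving out spots with a flag of -100 gave 39 higher in ADSC-ovary vs ADSC-iv and 8 lower in ADSC-ovary vs POF. Under omission of spots with a flag of -100, heat shock (-0.16) and luteal (-0.17) in ADSC-iv vs WT, luteal (-0.22) in ADSC-iv vs POF, smooth muscle (0.20) in ADSC-ovary vs POF and endothelial (-0.12), growth factor (0.29), MHC (0.15) and ovulation (0.093) in ADSC-ovary vs ADSC-iv no longer stood apart. Adipocyte (-0.26) in ADSC-ovary vs WT, adipocyte (-0.34) and housekeeping (-0.22) in ADSC-iv vs POF and adipocyte (-0.26) and growth factor (0.37) in ADSC-ovary vs POF newly stood apart. Under loess per print block, adipocyte (-0.099) and luteal (-0.025) in POF vs WT, theca (-0.11) in ADSC-ovary vs WT, smooth muscle (0.20) in ADSC-ovary vs POF and endothelial (-0.087) in ADSC-ovary vs ADSC-iv no longer stood apart. Surface epithelium (0.19) in POF vs WT, cell cycle (-0.14) in ADSC-ovary vs WT and heat shock (-0.18) and MHC (-0.19) in ADSC-iv vs POF newly stood apart. Under averaging of probes above background, lymphocyte (0.33) in POF vs WT, oxidative (-0.15) in ADSC-iv vs WT, luteal (-0.23) in ADSC-iv vs POF and endothelial (-0.12) in ADSC-ovary vs ADSC-iv no longer stood apart. Adipocyte (-0.22) in ADSC-ovary vs WT and housekeeping (-0.23) in ADSC-iv vs POF newly stood apart. Under scaling to one spread, luteal (-0.18) and lymphocyte (0.22) in ADSC-iv vs POF, smooth muscle (0.16) in ADSC-ovary vs POF and endothelial (-0.11) in ADSC-ovary vs ADSC-iv no longer stood apart. Granulosa (0.19), housekeeping (-0.23) and MHC (-0.26) in ADSC-iv vs POF and erythroid (-0.33) in ADSC-ovary vs POF newly stood apart. With random lists not matched on brightness, housekeeping (-0.17) and ovulation (-0.25) in ADSC-iv vs POF newly stood apart. A filter on both channels of all arrays left 18, 21 and 12 genes at 2-fold in the WT channel of the ADSC-iv and POF, ADSC-ovary and POF, and ADSC-ovary and ADSC-iv arrays, and 91.2% of genes lower in POF closer to WT on ADSC-iv.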

Other observations

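All observations in this part were chosen after the data had been seen, and the gene families were picked by name, 16 in number, of which 15 had enough measured genes; 50 of 90 family medians stood apart from random lists. Genes of the cytosolic ribosome were higher in ADSC-iv than in POF ovaries, with a median of 0.51 and 58 of 59 above 0, and the median was 0.42 with median centring and 0.47 in the authors' values. Against WT their medians were 0.08 in POF, 0.61 in ADSC-iv and 0.27 in ADSC-ovary, but 0.67, 1.14 and 0.89 with median centring. The 48 control spots for Rpl5, a ribosomal protein gene, which had no weight in the normalization, had mean log2 ratios of -0.09 (SD 0.09), 0.42 (SD 0.12) and 0.14 (SD 0.17) on the same arrays. Subunits of the respiratory chain (89 genes) were at 0.20 and 0.17 against POF in ADSC-iv and ADSC-ovary, and small nuclear ribonucleoproteins (18 genes) at 0.23 and 0.23, but with median centring these were 0.11 and 0.13, and 0.15 and 0.08. Mitochondrial ribosomal proteins were at 0.12 and 0.11, but at 0.01 and -0.02 with median centring. Membrane transporters of the Slc families, a large and mixed group, were at -0.13 and -0.08, and at -0.25 and -0.21 with median centring.

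Complement genes, which act in innate immunity, had medians of 0.47, 0.64 and 1.25 against WT in POF, ADSC-iv and ADSC-ovary (0.97, 0.85 and 1.47 with median centring), and 0.72 in ADSC-ovary against POF over 11 genes. Chemokine receptors were at 0.75 in the latter comparison over 5 genes. Proteasome subunits were at 0.17 there (0.07 with median centring) and 0.24 in ADSC-ovary against ADSC-iv. Collagen genes had a median of -0.20 in ADSC-iv against POF and -0.04 in ADSC-ovary against POF, and of -0.40 and -0.16 with median centring. The NLRP genes, several of which act in the egg, were at 0.68 in ADSC-iv against POF over 6 genes.

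Kitl, read by 1 probe, was at -1.26 in POF, -2.14 in ADSC-iv and -0.53 in ADSC-ovary against WT. H2-Ea, read by 2 probes, was at 2.40, 2.22 and 3.98. As background, C57BL/6 mice carry a promoter deletion and make no H2-Ea transcript, so what these probes read is unresolved.

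Among Y-linked genes, Ddx3y was above background in the Cy5 channel of both ADSC arrays and not of the POF array, and in the WT channel of none, with log2 ratios of 0.29 in ADSC-iv and 0.51 in ADSC-ovary. Eif2s3y was above background in Cy5 on the POF and ADSC-ovary arrays and in Cy3 on the ADSC-ovary array. Kdm5d was so in Cy5 on all 3 arrays and in Cy3 on the ADSC-iv array. Rbmy1a1, Sry, Usp9y, Uty and Zfy1 were not above background in any channel.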
